A study of Bos taurus with 12 samples.

How the data were processed

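The samples were bovine cumulus cells from slaughterhouse ovaries, collected complex by complex. Each oocyte was stained with a DNA dye and assigned to a germinal vesicle stage, and per the labels the cells of 10 complexes of 1 stage made 1 pool for RNA extraction. Amplified RNA of GV1, GV2 or GV3 was labelled with Cy5 and GV0 RNA with Cy3, and each pair was hybridised to 1 area of a slide with 4 areas, so that 3 slides held 4 arrays of GV1, GV2 and GV3. Each array has 45220 spots, of which 1426 are control spots (153 of them negative controls) and 43794 are probes with 1 spot each. No label says that the pools came from separate animals, so the p-values measure the spread between these pools.

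The deposited scanner tables give, per the file headers, the mean and median pixel intensity of each spot and its local background intensity in both channels, with no normalisation. They also hold a flag column of another kind (other than a signal), which per the file headers is 0 or 1 per spot, and the authors do not state its rule. The deposited series matrix holds log2 ratios, and the authors do not state how they were made. Its values were checked against the scanner tables: the log2 of the median Cy5 signal over the median Cy3 signal after within-array loess, without background correction, correlated with it at 1.00 (rounded) on each array across probes, with a median absolute difference of 0.000472. Its direction is stage over GV0, its array medians lie between -0.01 and 0.00, and no scaling between arrays was found. The series matrix served as an alternative only.

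The following choices were made before the data were examined: the test, the filter, the gene lists, the rule for named genes and the alternatives listed first in the last paragraph. The scanner's mean spot signals were used because replicate control spots varied less in them (median SD 0.0592 against 0.191 for median signals), which was seen before any comparison of groups. Background was corrected with normexp (offset 50) and ratios were normalised with loess within each array, in limma 3.58.1 under R 4.3.3, with statmod 1.5.0. Spots with the flag were left out. In a first version the normexp fit used all spots, as planned. Some spots with the flag had extreme signals that inflated the fitted background spread on 3 arrays, and after the first counts had been seen (165, 396 and 5304 probes for GV1, GV2 and GV3 against GV0, and 0 for each difference between stages) these spots were taken out of the fit. That version is kept among the alternatives. Probes were kept where a channel exceeded the mean plus 2 SD of the array's negative control spots on at least 3 of the 4 arrays of a stage, which left 36327 probes and removed 7467.

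Of the probes, 21790 carry 1 gene symbol and 22004 carry none, and no probe carries several. The array's 15229 distinct symbols were brought to current names with the RefSeq gene table of the ARS-UCD2.0 assembly, used for names only. Of these 14114 were current, 982 were renamed through synonyms and 133 matched neither way. A gene was represented by its brightest kept probe, for 13537 genes, of which 3355 had other kept probes.

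Log ratios of all 12 arrays were fitted in 1 limma model with a coefficient per stage. The model pools the spread of the 3 stages over 9 residual degrees of freedom and takes the arrays as independent. The stages share GV0 pools, as the area number below shows, so the residuals of different stages are correlated. The 9 degrees of freedom therefore overstate the information, and the p-values against GV0 may run low. Each coefficient was tested against 0, and the pairwise differences between coefficients were tested in the same model. P-values were adjusted with the Benjamini-Hochberg method over the kept probes, and an adjusted p under 0.05 counts as changed. GV0 is in the Cy3 channel of each array, so a dye effect of a probe stays in the ratios to GV0 and cancels in the differences between stages.

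The area number was tested as a pairing of the arrays. The Cy3 signals of the same area on different slides correlated with r between 0.988 and 0.997 across probes, those of different areas between 0.923 and 0.972. The GV0 RNA was therefore treated as 4 pools, 1 per area number, each used on the 3 slides. Deviations of the ratios from the stage mean correlated between 0.493 and 0.735 in the 12 array pairs of the same area, and 12 of 12 arrays were closest to their own area. In the Cy5 channel alone these values were 0.111 to 0.406 and 8 of 12. A fixed block for the area removes the spread between GV0 pools from the comparisons with GV0, so it was run as an alternative, as was the area as a random effect (within-area correlation 0.463).

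The model was tested on simulated data with shared pools. In 20 draws with no effect it called at most 2 probes in a comparison with GV0 and at most 1 in a difference between stages. The median share of probes with an unadjusted p under 0.05 in limma was 5.66% in these draws for GV1 against GV0, slightly more than the threshold implies. With 200 changed probes, 100 of each size, it recovered 31%, 46% and 40% of those changed by 0.5 (log2) in GV1, GV2 and GV3. Of those changed by 1 it recovered 74%, 76% and 85%, with 11, 6 and 15 unchanged probes called. In GV1 and GV3 the share of unchanged probes among the calls exceeded the 0.05 set for the adjusted p, and in GV2 it did not. Of 200 probes changed by 1 between GV1 and GV3, 57% were recovered in the difference, and 68% with the area block.

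Gene lists were written from textbook knowledge: gap junctions and oocyte contact, gonadotropin receptors with inhibins and granulosa differentiation, steroid synthesis, cholesterol synthesis, cumulus expansion and EGF-like factors, cell cycle, apoptosis and atresia, glycolysis and glucose uptake, oxidative phosphorylation, cytosolic ribosomal proteins, extracellular matrix, TGF-beta and BMP signalling, the IGF system, stress and immediate early genes, interferon response, hypoxia and angiogenesis, chromatin and histones, and markers of oocyte, theca and stroma, endothelium, leukocytes, red blood cells and mural granulosa. Each of the 23 lists was tested in each of the 6 comparisons with camera (two-sided, preset correlation 0.01) on 13455 genes with complete values, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. None of the 9 list calls held with the estimated correlation. The fry test, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called gap junctions and oocyte contact in GV1 and GV3, hypoxia and angiogenesis and the endothelial markers in all 3 stages, and cell cycle and chromatin in GV3. The mean, the median and the direction of the camera test differed in sign for 3, 9 and 7 lists in GV1, GV2 and GV3 against GV0 and for 3, 4 and 6 lists in the differences GV2 minus GV1, GV3 minus GV1 and GV3 minus GV2, none of them with a camera adjusted p under 0.05. Array means of the lists were also compared with two-sided exact permutation tests, which leave out the pairing of the arrays by area.

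The named genes were chosen by a fixed rule. Per comparison with GV0 they are up to 12 higher and up to 12 lower genes with the largest fold among those that passed and moved the same way on all 4 arrays, without uncharacterised loci. They further include the 10 genes changed in all 3 comparisons with the largest smallest fold, up to 4 members of each list with the smallest p, and FSHR, LHCGR, CYP19A1, STAR, GJA1, HAS2, PTGS2, INHBA, AMH, GREM1, TNFAIP6 and PTX3 where measured. LHCGR was named on the array but was not measured, since no probe with its name passed the filter on dim probes. Some genes that met the rule are not reported here: 1 with a large fold and part of the list members. Where fewer than 3 genes passed in a direction, the 5 with the smallest p are given as values.

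The alternatives fixed with these choices were no background correction, local background subtracted, median centring in place of loess, Aquantile between arrays, no filter and a strict filter on dim probes, the series matrix values, a fit on the arrays of a comparison alone, eBayes with trend and robust options, the area block, array weights, leaving out each array, a fold of at least 1.5, the mean over the probes of a gene and, for lists, the estimated correlation and fry. The planned normexp fit on all spots became an alternative after its counts had been seen. Added after the data had been seen were median spot signals, the area as a random effect and leaving out an area with its GV0 pool on all slides.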

Results

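RNA from bovine cumulus cells, the somatic cells that surround the oocyte, was measured on 12 2-colour microarrays. The cells were grouped by the chromatin configuration of the germinal vesicle of their oocyte, a series of 4 stages (GV0 to GV3) of increasing chromatin condensation. Each array carried GV1, GV2 or GV3 RNA in the Cy5 channel, 4 arrays per stage, and GV0 RNA in the Cy3 channel. The median spot signal per array lay between 132 and 230 in Cy5 and between 277 and 373 in Cy3. Between 59.9% and 83.8% of the 43794 probes lay above the level of the negative control spots in Cy5, and between 65.8% and 79.7% in Cy3. After the filter on dim probes, 36327 probes and 13537 named genes with a representative probe were tested, and the number of arrays limits the precision of every fold change below. Fold changes are log2 ratios of the stage over GV0, given with the standard error (SE) of the model over n = 4 arrays unless another n is stated.

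The comparison of GV1 with GV0 asked which transcripts of cumulus cells differ between oocytes at the first step of condensation and those with the least condensed chromatin. ANGPT2, a ligand of the endothelial TIE2 receptor, was higher in GV1 by 2.00 (SE 0.30, adjusted p = 0.00328). The lysozyme genes LYSB, LYZ2 and LYZ1, which encode antibacterial enzymes, were higher by 3.20 (SE 0.67), 2.18 (SE 0.46) and 1.52 (SE 0.27). PARM1, a mucin-like membrane protein, rose by 2.15 (SE 0.30) and NPY1R, a receptor of neuropeptide Y, by 2.00 (SE 0.40). The scavenger receptor gene OLR1 (2.01, SE 0.53), the transcriptional cofactor gene LMO2 (1.82, SE 0.39), the growth factor receptor gene PDGFRA (1.73, SE 0.45) and the secreted peroxidase gene GPX3 (1.64, SE 0.38) also rose, as did CCDC88C, which encodes a binding partner of Dishevelled (1.53, SE 0.28). SPP1, which encodes osteopontin, was at least 3.77-fold higher, since its GV0 signal was above background on 0 of the 4 arrays, and the GV0 signal of OLR1 was above background on 1. The calls of PDGFRA and GPX3 held in 19 and 21 of 30 alternatives. Those of SPP1, OLR1, LYSB and LYZ2 held in 17, 21, 22 and 22 of 29, while those of ANGPT2 and PARM1 held in 30 of 30. ISYNA1, the enzyme that makes inositol phosphate from glucose 6-phosphate, fell by 2.73 (SE 0.38). ANGPTL6, a secreted angiopoietin-like protein (-2.30, SE 0.34), HOPX, an atypical homeodomain protein (-2.15, SE 0.32), and DYM, a Golgi-associated protein (-2.08, SE 0.33), fell as well. SERPINA5, an inhibitor of serine proteases (-2.06, SE 0.53), PLAC9 (-2.04, SE 0.16), the secreted protein WFDC2 (-2.02, SE 0.20), TXNIP, a binding partner of thioredoxin (-1.74, SE 0.38), and the epithelial keratin KRT8 (-1.73, SE 0.42) were lower on all 4 arrays.

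In the gene groups, camera with a preset correlation called the cell cycle list and the interferon response list in GV1. Of the 47 measured cell cycle genes 0 rose, 6 fell and the others did not pass the test (6 fell adjusted over the list alone). Those that fell included AURKB, a mitotic kinase (-0.54, SE 0.10), CDC20, an activator of the anaphase-promoting complex (-0.65, SE 0.10), and the transcription factor gene E2F1 (-0.74, SE 0.15). The median of the cell cycle list was -0.30 (camera adjusted p = 6.33e-05), with adjusted p = 0.519 with an estimated correlation, the highest of its 28 alternatives, which began at 6.11e-08. The interferon response list had a median of 0.36 in its 25 genes (adjusted p = 0.0229, and adjusted p = 0.519 with an estimated correlation), although 0 members passed the limma test in either direction and the same number passed adjusted over the list alone. Its members MX1 and IFIH1 had values of 0.95 (SE 0.31, adjusted p = 0.0768) and 0.83 (SE 0.25, adjusted p = 0.0533). Without GV1 replicate 3 the interferon median was 0.07 (adjusted p = 0.640, the highest of 28 alternatives that began at 0.00320).

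Of 37 extracellular matrix genes 3 rose in GV1 and 1 fell (8 and 2 adjusted over the list alone). POSTN, COL6A2 and LAMB1, which encode periostin, a collagen VI chain and a laminin chain, were higher by 1.39 (SE 0.38), 0.64 (SE 0.17) and 0.82 (SE 0.23), and the elastin gene ELN fell by 0.39 (SE 0.07). The mean of the matrix list was 1.18 on the array GV1 3 and between -0.10 and 0.22 on the other GV1 arrays. In the TGF-beta and BMP list 4 of 28 rose and 0 fell (4 and 0 adjusted over the list alone), among them SKIL (0.90, SE 0.22) and the BMP antagonist gene NOG (0.76, SE 0.22). In the hypoxia and angiogenesis list 3 of 22 rose and 0 fell (5 and 0 adjusted over the list alone), with SPRY2, an inhibitor of receptor tyrosine kinase signalling, at 1.51 (SE 0.28). In the gap junction and oocyte contact list 2 of 15 rose and 1 fell, with the same counts adjusted over the list alone. These were CTNNB1 (beta-catenin, 0.77, SE 0.18), MYO10 (a filopodial myosin, 0.32, SE 0.08) and the connexin gene GJA5 (-1.10, SE 0.32). In steroid synthesis 3 of 19 genes rose and 3 fell (4 and 4 adjusted over the list alone), among them the cholesterol transport genes NPC2 (0.57, SE 0.10) and SCARB1 (0.56, SE 0.14) and the androgen synthesis gene CYP17A1 (-0.33, SE 0.07). In the stress and immediate early list 1 of 45 rose and 2 fell, with the same counts adjusted over the list alone, the latter being EGR1 (-1.61, SE 0.39) and the co-chaperone gene DNAJB1 (-1.55, SE 0.26). In apoptosis and atresia 1 of 27 rose and 4 fell (3 and 4 adjusted over the list alone), among them APAF1, a scaffold of caspase activation (1.12, SE 0.25), and FADD, an adaptor of death receptors (-0.62, SE 0.11). GREM1, a BMP antagonist of cumulus cells, fell by 0.47 (SE 0.13) and PGR, the progesterone receptor gene, rose by 0.96 (SE 0.26) in the cumulus expansion list, where 1 of 20 rose and 2 fell, with the same counts adjusted over the list alone. NR5A1, encoding steroidogenic factor 1, fell by 0.37 (SE 0.09) as the 1 of 15 genes that passed in the gonadotropin receptor, inhibin and granulosa differentiation list, with 1 adjusted over the list alone. H2AX, a histone variant, fell by 0.55 (SE 0.13) as the 1 of 33 chromatin genes that passed (0 adjusted over the list alone). No member passed in cholesterol synthesis (21 genes), glycolysis (23), oxidative phosphorylation (55), cytosolic ribosomal proteins (63), the IGF system (15) or red blood cell markers (7), and the count was also 0 adjusted over the list alone. At an unadjusted p under 0.05 in limma these lists held 2, 3, 5, 3, 2 and 1 members, and the interferon list 8. The camera adjusted p of the lists other than cell cycle and interferon response lay between 0.0549 and 0.962.

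Some markers of other cell types passed in GV1, where 1282 of the 13537 genes passed. Camera called none of the marker lists in GV1. Of 17 leukocyte markers 4 rose and 0 fell, with the same counts adjusted over the list alone, with BOLA-DRA (an MHC class II chain) at 1.36 (SE 0.37) and CD68 (a macrophage glycoprotein) at 0.88 (SE 0.24). Of 15 endothelial markers 0 rose and 4 fell, with the same counts adjusted over the list alone, with EGFL7 at -0.46 (SE 0.06). Among 17 theca and stroma markers PDGFRA rose and CYP17A1 fell (2 rose and 1 fell adjusted over the list alone). The mean of these markers was 1.05 on the array GV1 3, where the matrix list was also highest, and lay between -0.29 and 0.02 on the other GV1 arrays. The collagen genes COL1A1 and COL3A1 and the proteoglycan genes DCN and LUM belong to both lists. Among 12 mural granulosa markers GPX3 rose, with the same counts adjusted over the list alone. Among 20 oocyte markers ZP4 (0.32, SE 0.09) rose and MOS, a kinase of oocyte meiosis, fell by 0.98 (SE 0.09), with the same counts adjusted over the list alone. ZP4 was dim, at percentile 4.90 of the kept probes in Cy5, and was not above background in Cy5 on all 8 GV1 and GV3 arrays. FSHR (0.30, SE 0.17), CYP19A1 (0.04, SE 0.25), STAR (1.06, SE 0.56), GJA1 (0.08, SE 0.12), HAS2 (0.61, SE 0.28), PTGS2 (-0.29, SE 0.17), INHBA (0.41, SE 0.17), AMH (-0.12, SE 0.33), PTX3 (-0.22, SE 0.30) and TNFAIP6 (0.24, SE 0.26) did not pass, with adjusted p from 0.153 to 0.942.

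In limma, 3935 probes differed between GV1 and GV0 at an adjusted p under 0.05, 1615 higher and 2320 lower, which made 1282 genes (512 higher and 770 lower). The count was 10710 with the area number of the slide as a replicate block, which leaves out the spread between GV0 pools, and 1020 with probes above background in both channels on all arrays, 865 with a fold of at least 1.5, 305 with the series matrix values, 280 with median spot signals, 165 with outlier spots kept in the normexp fit and 0 with a limma fit on the 4 GV1 arrays alone (8515 at an unadjusted p under 0.05). Without 1 replicate, as a GV1 array or as an area on all slides, it was 1007 to 2630, and since GV0 was always labelled with Cy3, a dye effect of a probe remains in every ratio to GV0.

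The comparison of GV2 with GV0 addressed the next step of condensation. ANGPT2 was higher in GV2 by 1.90 (SE 0.30, adjusted p = 0.00402), and GPX3 by 1.92 (SE 0.38). GFRA1, a co-receptor of the neurotrophic factor GDNF, rose by 1.93 (SE 0.31) and LHX2, a LIM homeodomain transcription factor, by 1.89 (SE 0.29). PARM1 (1.74, SE 0.30), NPY1R (1.66, SE 0.40), LMO2 (1.58, SE 0.39) and SPRY2 (1.55, SE 0.28) also rose. CTTNBP2NL rose by 1.62 (SE 0.22), the threonyl-tRNA synthetase gene TARS3 by 1.62 (SE 0.43), YEATS4, a subunit of histone acetyltransferase complexes, by 1.49 (SE 0.16) and CADPS2, a factor of dense-core vesicle exocytosis, by 1.42 (SE 0.20). LYSB was higher by 2.63 (SE 0.67) on 3 of 4 arrays. Its call held in 20 of 29 alternatives and that of TARS3 in 20 of 30, while those of ANGPT2, LHX2 and YEATS4 held in 30 of 30. The tight junction gene CLDN11 fell by 3.04 (SE 0.68), with a GV2 signal above background on 2 arrays. ISYNA1 (-2.92, SE 0.38), ANGPTL6 (-2.56, SE 0.34), EGR1 (-2.35, SE 0.39), KRT8 (-2.27, SE 0.42) and GATM, the enzyme of the first step of creatine synthesis (-2.25, SE 0.35), fell. HOPX (-2.20, SE 0.32), WFDC2 (-2.09, SE 0.20), PHLDB1 (-1.97, SE 0.37), the glutathione transferase GSTA1 (-1.97, SE 0.50) and PLAC9 (-1.94, SE 0.16) were lower as well.

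Of the 47 cell cycle genes 0 rose and 7 fell in GV2 (9 fell adjusted over the list alone). Among them were AURKB (-0.57, SE 0.10), CDC20 (-0.59, SE 0.10) and RRM1, a subunit of ribonucleotide reductase (-0.47, SE 0.07). The list's median was -0.28 (camera adjusted p = 2.30e-05), with adjusted p = 0.897 with an estimated correlation, the highest of 28 alternatives that began at 1.04e-07. Of 45 stress and immediate early genes 1 rose and 7 fell (1 and 9 adjusted over the list alone), among them FOSB (-1.44, SE 0.30), DNAJB1 (-1.38, SE 0.26) and the thioredoxin reductase gene TXNRD1 (-0.56, SE 0.11). In hypoxia and angiogenesis 4 of 22 rose and 0 fell (5 and 2 adjusted over the list alone), including ANGPT1 (0.53, SE 0.14). In the interferon list 2 of 25 rose and 1 fell (3 and 1 adjusted over the list alone), namely IFIH1, a sensor of double-stranded RNA (0.89, SE 0.25, higher on 3 of 4 arrays), PARP14 (0.69, SE 0.19) and USP18 (-0.25, SE 0.07). In extracellular matrix 1 of 37 rose and 2 fell (0 and 2 adjusted over the list alone), which were POSTN (1.31, SE 0.38), the fibrillin gene FBN1 (-1.24, SE 0.29) and ELN (-0.41, SE 0.07). In the TGF-beta and BMP list 2 of 28 rose and 1 fell, with the same counts adjusted over the list alone, with the type I receptor gene ACVR1 at 0.77 (SE 0.20) and ID1, a target of BMP signalling, at -0.80 (SE 0.21). In the gap junction and oocyte contact list 2 of 15 rose and 1 fell, with the same counts adjusted over the list alone, with CTNNB1 at 0.71 (SE 0.18), the formin gene DAAM1 at 0.94 (SE 0.27) and GJA5 at -1.15 (SE 0.32). In steroid synthesis 2 of 19 rose and 1 fell (4 and 4 adjusted over the list alone), with NPC2 at 0.58 (SE 0.10) and HSD3B1 at 0.80 (SE 0.23). In apoptosis and atresia 0 of 27 rose and 3 fell, with the same counts adjusted over the list alone, with the stress sensor gene GADD45B at -1.62 (SE 0.33). The inhibin alpha gene INHA rose by 0.85 (SE 0.22) as the 1 of 15 genes that passed in its list, with 1 adjusted over the list alone. In the cumulus expansion list PGR rose by 1.12 (SE 0.26) and GREM1 fell by 0.46 (SE 0.13), 1 and 1 of 20 (1 and 2 adjusted over the list alone). H2AX (-0.77, SE 0.13) was the 1 of 33 chromatin genes that passed, with 1 adjusted over the list alone. IGFBP4, a binding protein of insulin-like growth factors (0.62, SE 0.13), was the 1 of 15 in the IGF list, with 1 adjusted over the list alone. COX6A1, a subunit of cytochrome c oxidase (0.23, SE 0.06), was the 1 of 55 in oxidative phosphorylation (0 adjusted over the list alone). No gene passed in cholesterol synthesis, glycolysis or cytosolic ribosomal proteins, nor adjusted over the list alone, and 2, 1 and 4 of their members had an unadjusted p under 0.05 in limma. The camera adjusted p of the lists other than cell cycle lay between 0.0619 and 0.979.

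Among the markers of other cell types in GV2, CD68 rose by 0.98 (SE 0.24) as 1 of 17 leukocyte markers, with the same counts adjusted over the list alone. Of 15 endothelial markers 0 rose and 4 fell (1 and 5 adjusted over the list alone), with EGFL7 at -0.38 (SE 0.06) and ESAM at -0.27 (SE 0.05). Of 20 oocyte markers ZP4 (0.45, SE 0.09) and NOBOX (0.31, SE 0.07) rose and MOS fell by 0.93 (SE 0.09), with 2 higher and 2 lower adjusted over the list alone. ZP4 and NOBOX lay at percentiles 4.90 and 32.3 of the kept probes in Cy5. Neither was above background in Cy5 on all 8 GV1 and GV3 arrays, the arrays on which this was checked. Of 7 red blood cell markers EPB42 (0.25, SE 0.06) and ALAS2 (0.24, SE 0.06) rose, with the same counts adjusted over the list alone. GPX3 was the 1 mural granulosa marker that rose, and in theca and stroma RGS5 (0.21, SE 0.05) rose and CYP17A1 (-0.30, SE 0.07) fell, with the same counts adjusted over the list alone. FSHR (0.40, SE 0.17), INHBA (0.55, SE 0.17), CYP19A1 (-0.09, SE 0.25), STAR (0.22, SE 0.56), GJA1 (-0.03, SE 0.12), HAS2 (0.55, SE 0.28), PTGS2 (-0.33, SE 0.17), AMH (-0.22, SE 0.33), PTX3 (-0.37, SE 0.30) and TNFAIP6 (-0.01, SE 0.26) did not pass, with adjusted p from 0.0611 to 0.993.

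In limma, 4271 probes differed between GV2 and GV0, 1969 higher and 2302 lower, which made 1397 genes (621 higher and 776 lower). The count was 10806 with the replicate block, 1139 with probes above background in both channels on all arrays, 1023 with a fold of at least 1.5, 505 with the series matrix values, 442 with median spot signals, 396 with outlier spots kept in the normexp fit and 0 with a limma fit on the 4 GV2 arrays alone (7548 at an unadjusted p under 0.05). Without 1 replicate, as a GV2 array or as an area on all slides, it was 1196 to 2968.

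The comparison of GV3 with GV0 set the most condensed configuration against the least condensed. EGR1, an immediate early transcription factor, fell by 2.80 in GV3 (SE 0.39, adjusted p = 0.00193), and DUSP1, a phosphatase of MAP kinases, fell by 2.72 (SE 0.38, adjusted p = 0.00186). ISYNA1 (-2.68, SE 0.38), ANGPTL6 (-2.61, SE 0.34), HOPX (-2.17, SE 0.32) and the surface glycoprotein gene CD99 (-2.11, SE 0.47) fell. PLAC9 (-2.01, SE 0.16), KRT8 (-1.99, SE 0.42), WFDC2 (-1.95, SE 0.20), PHLDB1 (-1.93, SE 0.37) and DAB2, an endocytic adaptor (-1.91, SE 0.47), were lower too. SLC39A8, a zinc transporter, rose by 2.44 (SE 0.67), LYSB by 2.43 (SE 0.67), ANGPT2 by 2.35 (SE 0.30) and PARM1 by 2.11 (SE 0.30). The log2 Cy3 level of SLC39A8 was 10.61, 10.91, 8.95 and 7.46 in GV0 pools 1 to 4. Its call held in 21 of 30 alternatives and that of LYSB in 15 of 29, while those of ANGPT2 and PARM1 held in 30 of 30. GPX3 (1.86, SE 0.38), PLA2G7, which hydrolyses platelet-activating factor (1.79, SE 0.48), LYZ2 (1.67, SE 0.46), GFRA1 (1.63, SE 0.31) and LHX2 (1.59, SE 0.29) rose as well. The calls of PLA2G7 and LYZ2 held in 21 of 30 and 15 of 29 alternatives. PELI1, a ubiquitin ligase of innate immune signalling, was higher by 1.62 (SE 0.19), GABARAPL1, an autophagosome protein, by 1.60 (SE 0.28) and TMEM37 by 1.56 (SE 0.33).

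Of the 47 cell cycle genes 0 rose and 24 fell in GV3 (30 fell adjusted over the list alone). They included AURKB (-1.15, SE 0.10), CDC20 (-0.96, SE 0.10), UBE2C, the ubiquitin-conjugating enzyme of mitotic exit (-1.40, SE 0.19), and RRM1 (-0.62, SE 0.07). The list's median was -0.67 (camera adjusted p = 9.15e-15), with adjusted p = 0.471 with an estimated correlation, the highest of 28 alternatives that began at 3.00e-20. Of 45 stress and immediate early genes 2 rose and 10 fell, with the same counts adjusted over the list alone, among them FOS (-1.46, SE 0.26) and TXNRD1 (-0.75, SE 0.11) beside EGR1 and DUSP1. Of 33 chromatin genes 0 rose and 5 fell, with the same counts adjusted over the list alone, with H2AX at -0.89 (SE 0.13), the chromatin protein gene HMGB1 at -0.58 (SE 0.14), EED, a subunit of Polycomb repressive complexes, at -0.49 (SE 0.12) and the histone methyltransferase gene SUV39H1 at -0.49 (SE 0.10). In oxidative phosphorylation 0 of 55 rose and 4 fell, with the same counts adjusted over the list alone, all of them subunits of complex I, with NDUFS7 at -0.73 (SE 0.19) and NDUFB7 at -0.53 (SE 0.11). In the TGF-beta and BMP list 3 of 28 rose and 2 fell, with the same counts adjusted over the list alone, with NOG at 0.93 (SE 0.22) and SKIL at 0.90 (SE 0.22) against ID3 at -1.85 (SE 0.36) and ID1 at -1.06 (SE 0.21). In extracellular matrix 3 of 37 rose and 3 fell (4 and 3 adjusted over the list alone), with COL6A2 at 0.81 (SE 0.17), the crosslinking enzyme gene LOX at 0.33 (SE 0.06) and FBN1 at -1.67 (SE 0.29). In hypoxia and angiogenesis 5 of 22 rose and 0 fell (6 and 0 adjusted over the list alone), with SPRY2 at 1.39 (SE 0.28) and the adrenomedullin gene ADM at 0.68 (SE 0.13). In steroid synthesis 3 of 19 rose and 0 fell (3 and 1 adjusted over the list alone), namely NPC1 (0.80, SE 0.22), NPC2 (0.40, SE 0.10) and the ferredoxin gene FDX1 (0.70, SE 0.19). In apoptosis and atresia 1 of 27 rose and 2 fell, with the same counts adjusted over the list alone, which were APAF1 (1.15, SE 0.25), FADD (-0.47, SE 0.11) and BCL2, an inhibitor of apoptosis (-0.45, SE 0.07). In the gap junction and oocyte contact list CTNNB1 (0.80, SE 0.18) rose and GJA5 (-1.11, SE 0.32) fell, 1 and 1 of 15, with the same counts adjusted over the list alone. NR5A1 fell by 0.50 (SE 0.09) as 1 of 15 in its list, with 1 adjusted over the list alone. IFIH1 (1.09, SE 0.25) rose and USP18 (-0.27, SE 0.07) fell among 25 interferon response genes, and IGFBP4 rose by 0.54 (SE 0.13) among 15 genes of the IGF system, with the same counts adjusted over the list alone. PGR (0.92, SE 0.26) was the 1 of 20 cumulus expansion genes and RPL30 (0.62, SE 0.17) the 1 of 63 ribosomal protein genes that passed, with 0 in both lists adjusted over the list alone. No gene passed in cholesterol synthesis or glycolysis, nor adjusted over the list alone, and 1 and 3 of their members had an unadjusted p under 0.05 in limma. The camera adjusted p of the lists other than cell cycle lay between 0.242 and 0.916.

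Among the markers of other cell types in GV3, CD68 (1.22, SE 0.24) and CD3E, a chain of the T cell receptor complex (0.24, SE 0.07), rose as 2 of 17 leukocyte markers. Of 15 endothelial markers ERG (0.19, SE 0.05) rose and EGFL7 (-0.46, SE 0.06) and ESAM (-0.21, SE 0.05) fell, and GPX3 rose among the mural granulosa markers. These counts were the same adjusted over the list alone. Of 20 oocyte markers ZP4 (0.33, SE 0.09) rose, and MOS (-1.08, SE 0.09) and the importin gene KPNA7 (-0.93, SE 0.24) fell (2 higher and 2 lower adjusted over the list alone). The Cy5 signal of ZP4 was dim, at percentile 4.90 of the kept probes, and not above background on all 8 GV1 and GV3 arrays. Of the 17 theca and stroma markers and the 7 red blood cell markers 0 passed, also adjusted over the list alone, and 3 and 0 had an unadjusted p under 0.05 in limma. HAS2 (0.91, SE 0.28), GREM1 (-0.39, SE 0.13), GJA1 (0.37, SE 0.12), INHBA (0.42, SE 0.17), FSHR (0.15, SE 0.17), CYP19A1 (-0.35, SE 0.25), STAR (0.16, SE 0.56), PTGS2 (-0.28, SE 0.17), AMH (0.17, SE 0.33), PTX3 (-0.03, SE 0.30) and TNFAIP6 (0.33, SE 0.26) did not pass, with adjusted p from 0.0595 to 0.963.

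**Figure D1:**
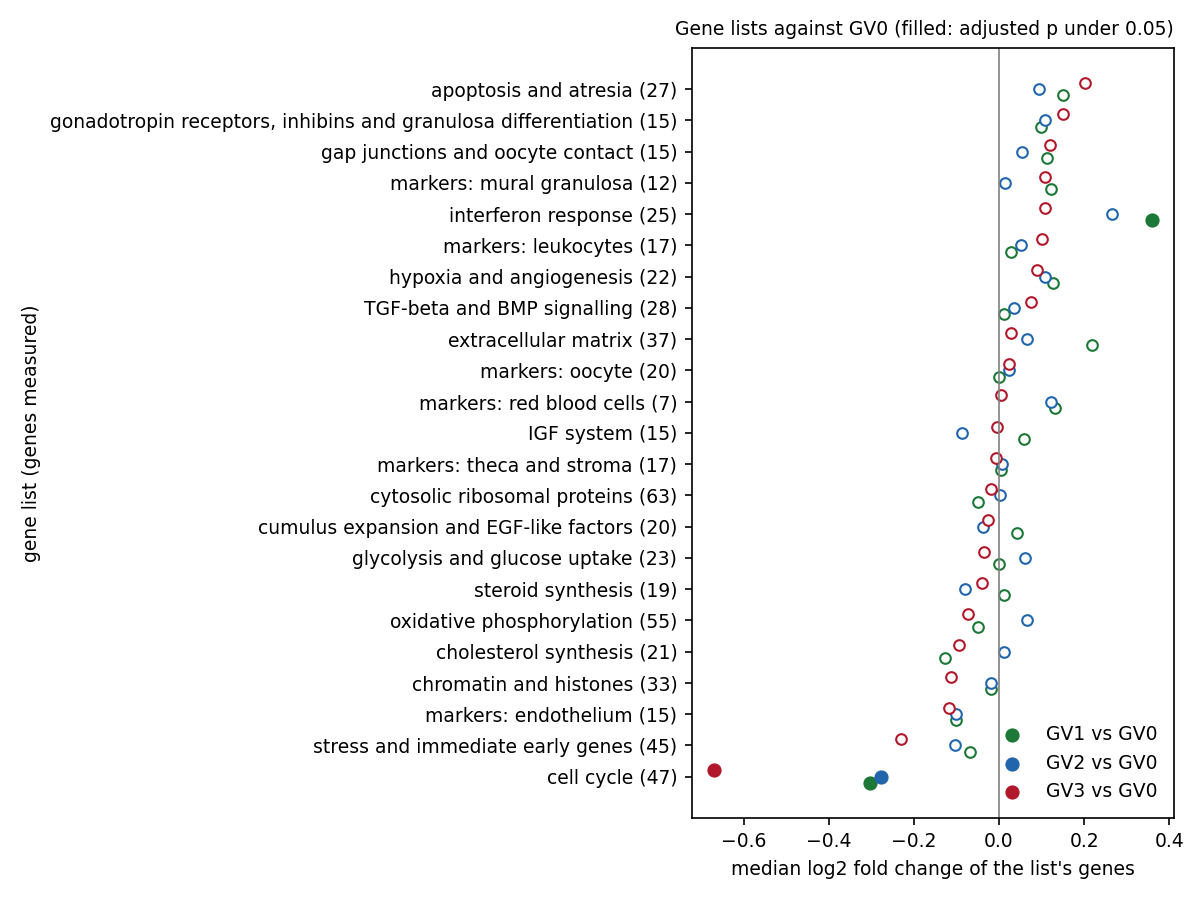
Median log2 fold change over GV0 (horizontal axis) of the genes of each list (vertical axis, number of genes measured in brackets) in GV1, GV2 and GV3, with filled points where the camera test with a preset correlation gave an adjusted p under 0.05. The cell cycle list lies lowest in all 3 comparisons, at -0.30, -0.28 and -0.67.

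In limma, 4396 probes differed between GV3 and GV0, 1857 higher and 2539 lower, which made 1489 genes (582 higher and 907 lower). The count was 10885 with the replicate block, 1742 with probes above background in both channels on all arrays, 1258 with a fold of at least 1.5, 743 with the series matrix values, 766 with median spot signals, 5304 with outlier spots kept in the normexp fit and 0 with a limma fit on the 4 GV3 arrays alone (8610 at an unadjusted p under 0.05). Without 1 replicate, as a GV3 array or as an area on all slides, it was 1416 to 2743.

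The 3 comparisons with GV0 had 2040 probes in common that changed the same way, 730 higher and 1310 lower, which made 662 genes (233 higher and 429 lower). ISYNA1, ANGPTL6, HOPX, WFDC2, PLAC9, PHLDB1 and GSTA1 were lower in GV1, GV2 and GV3, and ANGPT2 and LYSB were higher. Among the genes of the lists, MOS, EGFL7, ESAM, ELN, H2AX, AURKB, CDC20, FADD and GJA5 were lower and CTNNB1, NPC2, SPRY2, PGR, SKIL, CD68 and GPX3 higher in each of the 3 comparisons. PHLDB1 was at -1.98 (SE 0.37) in GV1, and GSTA1 at -1.84 (SE 0.50) in GV1 and -1.77 (SE 0.50) in GV3. The GSTA1 call held in 15, 20 and 16 of 30 alternatives in GV1, GV2 and GV3. On replicate 2 of GV1, GV2 and GV3 the GSTA1 ratio was -0.51, -0.01 and -0.91, the value closest to 0 in each stage. GV1 and GV2 shared 1077 higher and 1569 lower probes, against 87.5 and 147 for independent calls. GV1 and GV3 shared 945 and 1615, against 82.6 and 162, and GV2 and GV3 shared 947 and 1551, against 101 and 161. The 3 stages were compared with the same 4 GV0 pools, so their fold changes share chance values. Probes are not independent replicates. Across them the fold changes correlated with r = 0.867 (GV1 and GV2), 0.822 (GV1 and GV3) and 0.807 (GV2 and GV3). Simulated data with no effect and shared pools gave 0.466, 0.466 and 0.465. The simulation called at most 2 probes in a comparison, so its 0 shared calls say nothing about the shared counts. It used a within-area correlation of 0.463 for every probe, and this setting fixed the simulated correlations of the fold changes. Ratio deviations of the same area correlated between 0.493 and 0.735. The simulation may therefore understate what shared pools add, and its correlations are no independent measure of it. The covariances were 0.0776, 0.0772 and 0.0769, against 0.0144, 0.0144 and 0.0143 in the simulation. When each stage was given 2 pools that the other stage did not use, the mean covariance was 0.0543, 0.0549 and 0.0557, and limma made 0 calls in any stage in these fits on 2 arrays per stage, with 1567 to 2425 probes at an unadjusted p under 0.05 in both stages, of which 85.4% to 96.3% had the same sign.

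**Figure D2:**
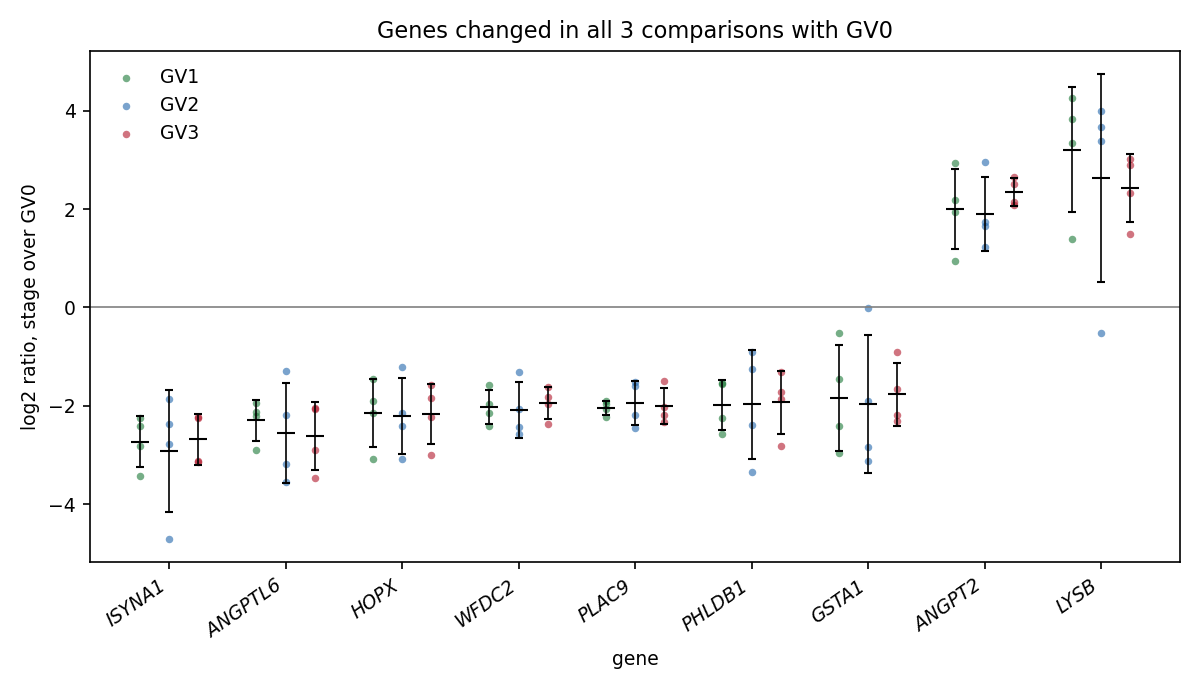
Log2 ratio over GV0 (vertical axis) of 9 genes that changed the same way in all 3 comparisons, with 1 point per array and bars for the mean and the SD of the 4 arrays of GV1, GV2 and GV3. ANGPT2 lies above 0 on all 12 arrays, and LYSB lies at -0.52 on 1 GV2 array.

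The stages were also compared with each other through their common GV0 reference, which cancels a constant dye effect of a probe. Between GV1 and GV2 the genes with the smallest p were BRWD3 (0.97, SE 0.24), the thioredoxin-related transmembrane protein gene TMX3 (0.83, SE 0.19), SAMD12 (0.45, SE 0.11), the corticotropin-releasing hormone receptor gene CRHR1 (0.23, SE 0.06) and SOX2 (0.20, SE 0.06) with higher values in GV2. ADGRL1 (-0.46, SE 0.14), HOOK1 (-0.37, SE 0.11), the nucleoside transporter gene SLC28A2 (-0.31, SE 0.08), TLR1 (-0.26, SE 0.08) and HPD (-0.22, SE 0.07) had lower values, and none of these genes passed. In limma 0 probes passed, with 411 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00, and the number of list members that passed adjusted over the list alone was 0. The extracellular matrix list had a median difference of -0.20 in 37 genes, lower in GV2 (camera adjusted p = 0.00203), with adjusted p = 0.486 with an estimated correlation. Over its 28 alternatives the adjusted p ran from 1.66e-05 to 0.907, and without GV1 replicate 3, the array with the high theca and stroma markers, the median was -0.06 (adjusted p = 0.608). Without GV2 replicate 4 it was -0.08 (adjusted p = 0.0312). The stress and immediate early list had a median of -0.10 in 45 genes (adjusted p = 0.0439), with adjusted p = 0.689 with an estimated correlation and 0.000227 to 0.907 over its alternatives. Without replicate 1 on all slides that median was 0.05 (adjusted p = 0.509). The call was lost in 15 of 28 alternatives. These included the replicate block (adjusted p = 0.104), median centring (0.0501), no filter (0.0625), the series matrix values (0.108) and median spot signals (0.0787). Others were the fits without GV1 replicate 1 or 4, GV2 replicate 1, GV3 replicate 2, 3 or 4, or replicate 4 on all slides (adjusted p from 0.0537 to 0.664). The median was -0.02 without GV1 replicate 1, -0.06 without GV1 replicate 4, -0.20 without GV1 replicate 2, -0.16 without GV2 replicate 3 and -0.17 without replicate 2 on all slides.

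Between GV1 and GV3 the cell cycle list had a median difference of -0.35 in its 47 genes, lower in GV3 (camera adjusted p = 7.68e-14), with adjusted p = 0.429 with an estimated correlation and 3.59e-23 to 0.828 over its alternatives. Its array means were -0.32 (SD 0.25) in GV1 and -0.67 (SD 0.33) in GV3. The mean difference of -0.35 was in the same direction in 4 of 4 areas, and a two-sided exact permutation test of the array means gave p = 0.143 (0.914 adjusted over the lists), where 0.0286 is the smallest that 4 against 4 arrays allow. This test, here and between GV2 and GV3, took the arrays as unpaired, although the area number pairs them. AURKB (-0.60, SE 0.15) and KIF2C, a mitotic kinesin (-0.72, SE 0.16), were among the genes with the smallest p and lower values in GV3, with the creatine kinase gene CKB (-0.99, SE 0.24), RABL3 (-0.61, SE 0.16) and IHH, encoding Indian hedgehog (-0.59, SE 0.14). CDH8 (0.75, SE 0.19), CNPY4 (0.60, SE 0.12), SAMD12 (0.42, SE 0.11), NEMP1 (0.40, SE 0.07) and RAB27B (0.33, SE 0.09) had higher values. None of these genes passed in limma, where 0 probes were called, 684 had an unadjusted p under 0.05 and the smallest adjusted p was 1.00. The stress and immediate early list had a median of -0.17 (adjusted p = 0.0286), with adjusted p = 0.851 with an estimated correlation and 3.00e-05 to 0.962 over its alternatives. Without replicate 1 on all slides that median was 0.02 (adjusted p = 0.757). The call was lost in 8 of 28 alternatives, among them the replicate block (adjusted p = 0.124), the series matrix values (0.126) and median spot signals (0.139). It was also lost without GV1 replicate 1 (median -0.08, adjusted p = 0.645) and without GV3 replicate 1 (median -0.05, adjusted p = 0.576).

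Between GV2 and GV3 the cell cycle list had a median difference of -0.37, lower in GV3 (camera adjusted p = 1.87e-11), with adjusted p = 0.658 with an estimated correlation and 5.18e-20 to 0.695 over its alternatives. Without GV3 replicate 1 the median was -0.24 (adjusted p = 0.000102). The mean difference was -0.34 and in the same direction in 3 of 4 areas, with p = 0.143 in a two-sided exact permutation test (1.00 adjusted over the lists). KLHL22 (0.81, SE 0.19), CNPY4 (0.57, SE 0.12), PCBP3 (0.35, SE 0.07), ANKRD44 (0.35, SE 0.08) and PIP5KL1 (0.33, SE 0.08) had higher values in GV3. TMX3 (-0.95, SE 0.19), IHH (-0.59, SE 0.14), the atrial myosin light chain gene MYL4 (-0.48, SE 0.11), LRRC40 (-0.41, SE 0.08) and JAGN1 (-0.37, SE 0.08) had lower values, and none of these genes passed. In limma 0 probes were called, 1097 had an unadjusted p under 0.05 and the smallest adjusted p was 1.00. Without GV2 replicate 4 limma called 1 probe. With the replicate block the probes at an unadjusted p under 0.05 were 1477 (GV1 and GV2), 2826 (GV1 and GV3) and 3815 (GV2 and GV3), and limma called 0 in each. Without the block the spread of the GV0 pools, which cancels in these differences, stays in the error, so the limma p-values run high. Each slide held the 4 arrays of 1 stage, so slide and stage cannot be told apart in these differences, and the camera adjusted p of the lists not given here lay between 0.0903 and 0.987.

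**Figure D3:**
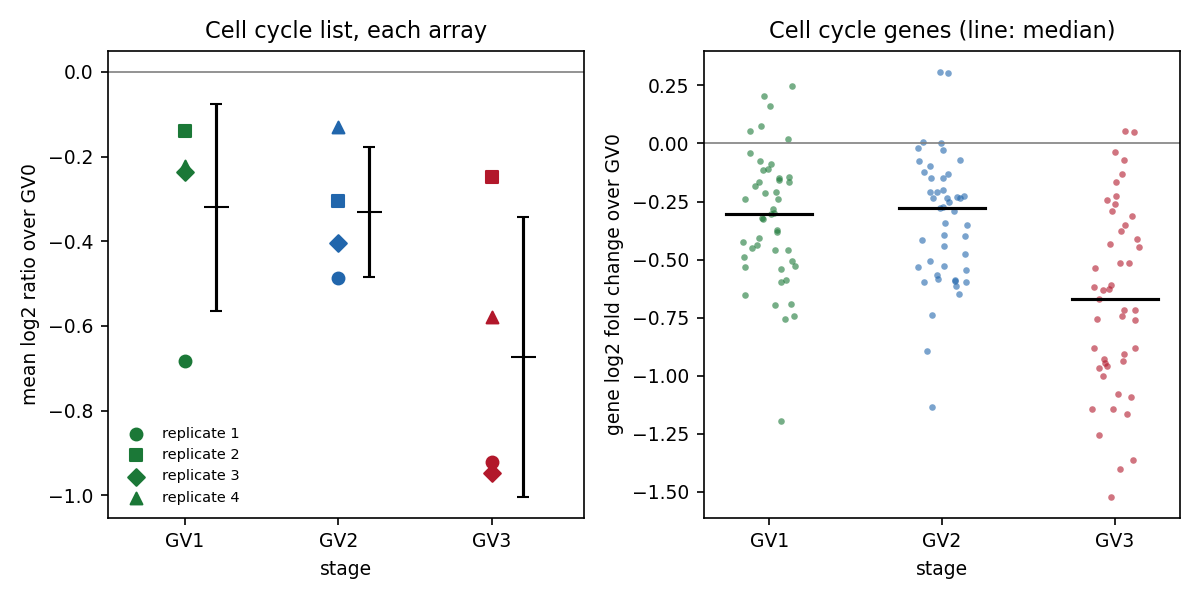
Cell cycle list over GV0. The left panel gives the mean log2 ratio of the 47 genes on each array (1 point per array, bars for the mean and SD of 4 arrays), and the right panel gives the log2 fold change of each gene with the median as a line. The array means of GV3 lie between -0.95 and -0.25, and those of GV1 between -0.68 and -0.14.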

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

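The tests of oocyte markers, of a dye effect on single probes and of a single GV0 pool were chosen only after the result they bear on was seen; the others were chosen before.

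The cell cycle list was lower in GV3 than in GV1, with a median difference of -0.35, and lower in GV3 than in GV2, with -0.37 (-0.24 without GV3 replicate 1), and was singled out because these differences passed the camera test at a preset correlation, with adjusted p = 0.429 and 0.658 with an estimated correlation. The same GV0 pools were hybridised on all slides, and their channel shifted by -0.021 (median absolute deviation 0.04) for these 47 genes from the GV1 to the GV3 slide, so a slide difference carried by that channel does not account for it. The lowest median of 10000 lists matched on brightness was -0.14, which argues against the brightness of the probes. Of the 8 oocyte markers above background on all 8 arrays 7 were lower in GV3, with a median of -0.071 (median absolute deviation 0.09) and KPNA7 at -0.58, but only 2 were a doubling brighter than the brightest marker that failed background, so less oocyte RNA in GV3 stays open. A lower share of dividing cumulus cells around GV3 oocytes may explain the pattern but was not tested, and a slide difference in the Cy5 channel stays open because each slide holds 1 stage.

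The fold changes of the 3 comparisons with GV0 resembled each other, with 2040 probes changed the same way in all of them. Shared GV0 pools add to this, but stage pairs that used different pools kept 70.1%, 71.1% and 72.4% of the covariance in the mean of 6 divisions of the pools (lowest single covariance 0.0451, against 0.0776 with all pools), which argues against the shared pools as the whole cause. Of the 262 other probes of the shared genes 73.3% had the same sign (95% interval 67.5% to 78.5%), against 61.5% for other genes. Only 14.9% of the 262 were themselves called in all 3 comparisons in the same direction, against 3.76% for other genes. The 262 probes belong to 185 genes and the interval takes them as independent, so it may be too narrow. The other genes were not matched on the size of the fold. A dye effect of single probes may therefore be part of the pattern and cannot be told apart from a difference between GV0 and later stages, because GV0 was always in Cy3 and the share lies under the bound of 75% that was set against it. A biological difference of GV0 from all later stages stays open and untested.

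Of the stress and immediate early genes 10 were lower in GV3 than in GV0, EGR1, DUSP1, FOS, FOSB, IER2, NR4A1, DNAJB1, TXNRD1, DDIT4 and SOD2, with a median of -1.41. The median of all 45 measured members was -0.23 (17 positive and 28 negative, camera adjusted p = 0.242), so the list as a whole was not called. The highest median Cy3 excess of a GV0 pool over the other 3 was 0.458 for the 10 genes (largest in a single gene 0.90), where 1 pool alone would need 5.64. The 10 genes were chosen because they passed in limma, and a fall that came from 1 pool alone would hardly pass. The excess therefore cannot decide whether 1 GV0 pool had high levels. A stage difference in immediate early transcription, a difference in the time from collection to freezing, which the labels do not give, and a dye effect may each contribute and were not tested.

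The extracellular matrix list was lower in GV2 than in GV1 by a median of -0.20, by the same kind of test of the difference, and by -0.06 without GV1 replicate 3, whose array mean was 1.18 for this list and 1.05 for the theca and stroma markers (at most 0.22 and 0.02 on the other GV1 arrays). The stress and immediate early list was lower in GV2 than in GV1 by -0.10. It was also lower in GV3 than in GV1 by -0.17. Without replicate 1 on all slides these 2 medians were 0.049 and 0.022, and with the area block neither was called (adjusted p = 0.104 and 0.124, ranges over the alternatives 0.000227 to 0.907 and 3.00e-05 to 0.962). None of these list differences held with an estimated correlation (adjusted p from 0.486 to 0.851). LYSB had a log2 ratio of -0.52 on the array GV2 1, far from the other GV2 arrays at 3.39 to 3.99. The SD of the log2 ratios was 0.47 on the array GV3 4, against 0.44 to 0.45 on the other GV3 arrays. With 131 groups of 4 arrays examined, chance alone singles out about 1 in 20, or 6.55, and 2 were found.

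For the comparisons with GV0 the 8 sign patterns of 4 arrays are too few for a share under 0.05, and the real pattern called 3935, 4271 and 4396 probes in GV1, GV2 and GV3 against a highest other count of 0 in each, so that 1 of 8 patterns reached the real count. For the differences between stages the counts at an unadjusted p under 0.05 do not exclude chance: 30, 28 and 27 of 35 splits of the 8 arrays reached the real 411, 684 and 1097 for GV1 and GV2, GV1 and GV3, and GV2 and GV3, and the highest others were 5672, 5296 and 4980. Splits that call several times the real count point to a structure of the samples, here the area number that pairs the arrays, since the splits with the most calls put both arrays of an area on the same side. Among the 8 splits that part all pairs, with the area block, the real counts were 1477 (the highest other 2728, with 3 splits at or above the real one), 2826 (the highest other 1828) and 3815 (the highest other 3098).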

How the results depend on the processing

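Median spot signals, the area as a random effect and the areas left out on all slides were chosen only after the data were seen. The normexp fit with the outlier spots kept was the version set beforehand, and taking them out, as in the report, was chosen after its counts were seen. Where both called a probe, the analysis given in the report and an alternative had it in opposite directions for only 1 probe, in GV2 with the series matrix values. No background correction gave 4573, 4770 and 4298 probes for GV1, GV2 and GV3 against GV0, and with local background subtraction, no filter, median centring, trend and robust options, array weights or a random area the total counts stayed within 1.5 times. With median centring the lower probes were 3572 against 2320 in GV1 and 3637 against 2302 in GV2, and the higher ones 2147 against 1615 and 2401 against 1969. Trend and robust options mainly removed higher probes, which were 1093, 1446 and 1370 in GV1, GV2 and GV3 against 1615, 1969 and 1857. The lower ones were 2192, 2205 and 2454 against 2320, 2302 and 2539. Aquantile leaves the log ratios as they were, so it moved nothing and says nothing about stability.

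The counts for GV1, GV2 and GV3 against GV0 (3935, 4271 and 4396) moved as follows, and the cause was not tested unless stated. They were 1020, 1139 and 1742 with probes above background in both channels on all arrays, where fewer probes were tested. They were 305, 505 and 743 with the series matrix values, and 280, 442 and 766 with median spot signals, whose replicate control spots vary more. With outlier spots kept in the normexp fit they were 165 and 396 in GV1 and GV2 and 5304 in GV3. With the area as a replicate block they were 10710, 10806 and 10885, since the block takes the spread between GV0 pools out of the error; it called 0 probes in the differences between stages, and all calls without it were among those with it (3935, 4271 and 4396 shared). A fit on the arrays of the comparison alone, with fewer residual degrees of freedom, gave 0, 0 and 0 in limma (8515, 7548 and 8610 at an unadjusted p under 0.05), and a fold of at least 1.5 gave 865, 1023 and 1258.

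Without GV1 replicate 1, 2, 3 or 4 the GV1 count was 2489, 1682, 1774 and 1299. Without GV2 replicate 1, 2 or 4 the GV2 count was 2671, 2050 and 1672, and without replicate 3 it was 2968. Without GV3 replicate 1, 2, 3 or 4 the GV3 count was 2665, 2337, 2443 and 1910. Without replicate 1 (the area on all slides) the counts were 2630, 2372 and 2743, without replicate 2 they were 1007, 1196 and 1416, without replicate 3 they were 1295, 2171 and 1967, and without replicate 4 they were 1086, 1233 and 1604. Over every array left out, of other stages too, and every area left out, the range was 1007 to 3881 in GV1, 1196 to 3906 in GV2 and 1416 to 4383 in GV3. The differences between stages stayed at 0 in every alternative except GV3 minus GV2, with 1 probe without GV2 replicate 4.

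The number of list calls was 9 of 138 tests. It was 20 with median centring, 0 with an estimated correlation, and 8 to 14 without 1 replicate (14 without GV1 replicate 2 and 14 without GV1 replicate 4). The median of the stress and immediate early list reversed without replicate 1, to 0.049 in GV2 minus GV1 (adjusted p = 0.509, range 0.000227 to 0.907 over its alternatives) and to 0.022 in GV3 minus GV1 (adjusted p = 0.757, range 3.00e-05 to 0.962). Over the arrays and areas left out these medians ran from -0.199 to 0.049 and from -0.211 to 0.022. The block ended both stress list calls (adjusted p = 0.104 and 0.124) and no other gene or list lost its call with it, while the oxidative phosphorylation list gained a call in GV2 minus GV1 and GV3 minus GV2 (adjusted p = 0.00456 and 0.0278, but adjusted p = 0.732 and 0.528 with an estimated correlation). The interferon call in GV1 and the extracellular matrix call in GV2 minus GV1 were lost without GV1 replicate 3 (adjusted p = 0.640 and 0.608, ranges 0.00320 to 0.640 and 1.66e-05 to 0.907), and the cell cycle call in GV1 with median centring (adjusted p = 0.0522, range 6.11e-08 to 0.519). Over 28 alternatives these 3 calls were lost in 6, 4 and 3. The medians of the cell cycle list stayed negative in all 28 alternatives, from -0.40 to -0.19 in GV1, -0.35 to -0.18 in GV2 and -0.81 to -0.56 in GV3.

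EDN1 in GV3 against GV0 reversed to -0.025 with the series matrix values and to -0.052 with median spot signals. Of the 150 gene results called, 17 to 30 lost the call without 1 array, 49 to 88 without 1 area, 65 with the outlier spots kept in the normexp fit, and 65 and 69 with median spot signals and the series matrix values, beside the reversal of EDN1 in each of the last 2. Trend and robust options ended 20 of the calls. With probes above background in both channels on all arrays 92 kept the call and 13 lost it. The other called results fell out of that test, since their probes did not pass its filter. Of the 24, 25 and 25 genes selected for their size or sharing in GV1, GV2 and GV3, 8, 11 and 11 kept the call in every alternative run on genes, among them PLAC9, WFDC2, ISYNA1, HOPX and ANGPT2. The fit on the arrays of a comparison alone was not among these alternatives, and it called 0 probes in GV1, GV2 and GV3.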

Other observations

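These observations were made after the data had been seen, and no test of them was planned.

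The GV0 pools differed from each other in named genes, a spread that enters every ratio to GV0 and is no difference between stages. TRIB1, a pseudokinase of the COP1 ubiquitin ligase, had log2 Cy3 levels of 12.32 and 12.96 in GV0 pools 1 and 2 and of 8.37 and 9.50 in pools 3 and 4, with an SD of 0.04 between slides. FOSL1, a subunit of the AP-1 transcription factor, had 12.51, 12.51, 9.69 and 8.54, SRXN1, a sulfiredoxin, had 12.35, 13.01, 9.51 and 9.48, and the amino acid transporter gene SLC7A5 had 12.72, 13.22, 11.59 and 10.13. TNFRSF12A, a receptor of the TNF family, had 10.83, 12.03, 8.27 and 7.75. BOLA-DQB, an MHC class II chain, had 10.94, 7.55, 12.34 and 10.08, and AXL, a receptor tyrosine kinase, 7.28, 11.39, 8.96 and 10.49. In the mean over the cholesterol synthesis list, the pools lay at 0.53, 0.21, -0.23 and -0.52 relative to their common mean, with a largest SD between slides of 0.04, and in the cell cycle list at 0.16, -0.29, 0.10 and 0.03. Between pairs of GV0 pools 13445 to 15944 probes differed in limma, over a spread that is technical only.

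A set of probes followed the area number in both channels. On 464 probes the range between areas exceeded 1.5 (log2) in both channels, and 315 of these with a correlation over 0.95 between the channels stood in the same order of areas, the commonest of 24 possible orders, with the lowest level in area 1, then areas 3, 2 and 4. Their median Cy3 levels were 8.52, 10.44, 9.06 and 11.74 in areas 1 to 4, and their median Cy5 levels 8.61, 10.21, 8.91 and 11.01. USP32 (7.89, 10.28, 8.62 and 11.91 in Cy3), FSCN2 (7.76, 10.00, 8.12 and 11.67) and AQP11 (8.24, 10.75, 9.01 and 12.11) are among the 140 named probes. Of these 315 probes 3, 0 and 0 were called in limma in GV1, GV2 and GV3 against GV0. These are values only, with no explanation tested.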
